A study of Vitis vinifera with 18 samples.

How the data were processed

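The series covers ripe berries of the red grapevine varieties Aglianico and Cabernet Sauvignon (Vitis vinifera), grown in the open field at 3 sites in southern Italy: Campania, Molise and Sicily. Per the labels' protocols, 10 berries per biological replicate were ground without seeds, polyadenylated RNA was selected, and libraries were made with a NEBNext Ultra kit. The design text gives 3 biological replicates for each of the 6 combinations of variety and site, so 18 libraries were analysed. Samples were grouped from the titles. The column of 1 Cabernet Sauvignon Sicily library carried no legible replicate number and was matched to its group only; it is called the unnumbered library. All 18 columns were mapped, and 0 were left aside.

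The authors deposited a table of expected counts (estimated read counts that need not be whole) for 97442 transcript clusters, not scaled to a common depth. Between 5.6% and 7.78% of the values of a library were not whole numbers. The submitters' processing notes name CASAVA 1.8, RSEM and DESeq2 without saying what each was used for. The aligner, the assembler and any genome build are not given in the sources used here. The clusters carry numbers in place of gene names, and 0 of their identifiers matched the RefSeq gene table used here (assembly GCF_030704535.1). For that reason 32 lists of genes, written before the data were examined (pigment, stilbene, stress, hormone, sugar, cell wall and other pathways, with seed storage genes as a marker of other tissue), could not be tested: 0 lists gave a value. Where related genes or alleles share sequence, the estimation of counts can divide reads between clusters, so the level of a single cluster is uncertain to that extent. A cluster that is absent from 1 variety may also be a diverged allele counted under another number. Climate records and berry quality traits were not analysed here.

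Expected counts were rounded to whole numbers. Totals per library ranged from 22637307 to 31859647. The lowest chi-square per degree of freedom between any 2 libraries was 21.7 (clusters with a summed count of at least 20), so no library was a second copy of another. Clusters were kept by the filterByExpr function of edgeR 4.0.16 with the 6 groups, which left 27519 clusters and removed 69923. The kept clusters held 91.9% to 99.8% of the counts of a library. Scaling factors by the trimmed mean of M values (TMM) ranged from 0.62 to 1.22. Levels are given as CPM, computed here from the deposited expected counts and the TMM factors; presence, absence, shares of counts and the correlations used to judge the doubted Cabernet Sauvignon Sicily libraries used CPM from the unscaled totals.

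Differences were tested with the quasi-likelihood test of edgeR (glmQLFit and glmQLFTest, robust shrinkage, R 4.3.3), with all 18 libraries in 1 fit of 6 group means. Adjusted p-values are by Benjamini and Hochberg over the clusters tested, and a cluster was called at an adjusted p under 0.05. The tests were each pair of sites within a variety, any site difference within a variety (2 degrees of freedom), Cabernet Sauvignon against Aglianico at each site and averaged over sites, and the interaction of variety and site, overall (2 degrees of freedom) and for each pair of sites. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. The rule for naming clusters, set before the data were examined, allowed at most 2 higher and 2 lower per comparison where identifiers carry no gene names: the largest log2 fold changes among called clusters with a mean of at least 5 CPM and no overlap between the groups. Where the lower group held no count, the fold is the mean of the higher group against 3 counts summed over the lower group. It is a lower bound for counting error in the lower group only, and leaves out the spread within the higher group. With 1 to 3 counts in the lower group, the ratio of means is given with a 95% Poisson interval, which covers counting error only.

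The test was tried on simulated counts made for Aglianico Molise against Campania, with 26477 clusters. It recovered 12.2% of clusters changed 2-fold, 54.2% changed 4-fold, 65.3% changed 8-fold and 81.6% changed 16-fold, and 1% of its calls were false. Apart from these changes the simulated libraries shared 1 mean profile, with no variety difference and no library of another variety. The shares therefore need not hold for the real libraries. Principal components used log2 CPM (prior count 2) of the 1000 most variable clusters. Overlaps between lists of called clusters are given beside the number that independent lists of the same sizes would share. The lists come from 1 fit that estimates the spread of a cluster over all groups. Some sharing beyond that number can therefore arise without shared effects. A set of 87 clusters was defined as reaching 500 CPM in some library and staying at or under 0.1 CPM in another.

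Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), no robust shrinkage, an added fold threshold, library sizes without the 20 most abundant clusters, fits on a single variety or on 2 groups, a replicate block, and each library left out in turn. Chosen after seeing the data were fits without 2 Cabernet Sauvignon Sicily libraries, without these and the library labelled Aglianico Campania replicate 3, without the 87 clusters, and without a block over the 17 numbered libraries. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.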

Results

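Gene expression in fully ripe berries was measured by RNA sequencing in 2 red grapevine varieties, Aglianico, a variety of southern Italy, and Cabernet Sauvignon, an international variety. Each variety was sampled at 3 sites, Campania, Molise and Sicily, with 3 biological replicates per variety and site, each a pool of 10 berries without seeds. The question named by the design was how the 2 genotypes respond to the growing environment. The 18 libraries held between 22637307 and 31859647 expected counts. Totals were 22637307 to 31859647 in Aglianico Campania, 22936262 to 23546953 in Aglianico Molise and 22791077 to 26264297 in Aglianico Sicily (n = 3 each). Cabernet Sauvignon had 24050462 to 28141388 at Campania, 23198429 to 26400506 at Molise and 25331142 to 29938459 at Sicily (n = 3 each). The features were 97442 transcript clusters, of which 27519 were tested.

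The first principal component of the 1000 most variable clusters held 38.2% of their variance and parted 8 of the 9 Aglianico libraries, at scores of -76.7 to -58.73, from the 9 Cabernet Sauvignon libraries, at 23.05 to 84.43. The second held 19.4% and set Aglianico Molise (51.32 to 85.02) against Aglianico Sicily (-74.97 to -49.03). The library labelled Aglianico Campania replicate 3 lay among the Cabernet Sauvignon libraries at 37.95. Its mean correlation across clusters was 0.972 with the Cabernet Sauvignon Campania libraries and 0.887 with the other libraries of its labelled group. Over all 27519 tested clusters and all 18 libraries, variety took 23% of the variance, site 23.4%, their interaction 19.2% and the spread within groups 34.5%. The terms were fitted in that order. Without the library labelled Aglianico Campania replicate 3 and 2 Cabernet Sauvignon Sicily libraries described below (the 3 doubted libraries), variety took 29.5%, site 25.8%.

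**Figure D1:**
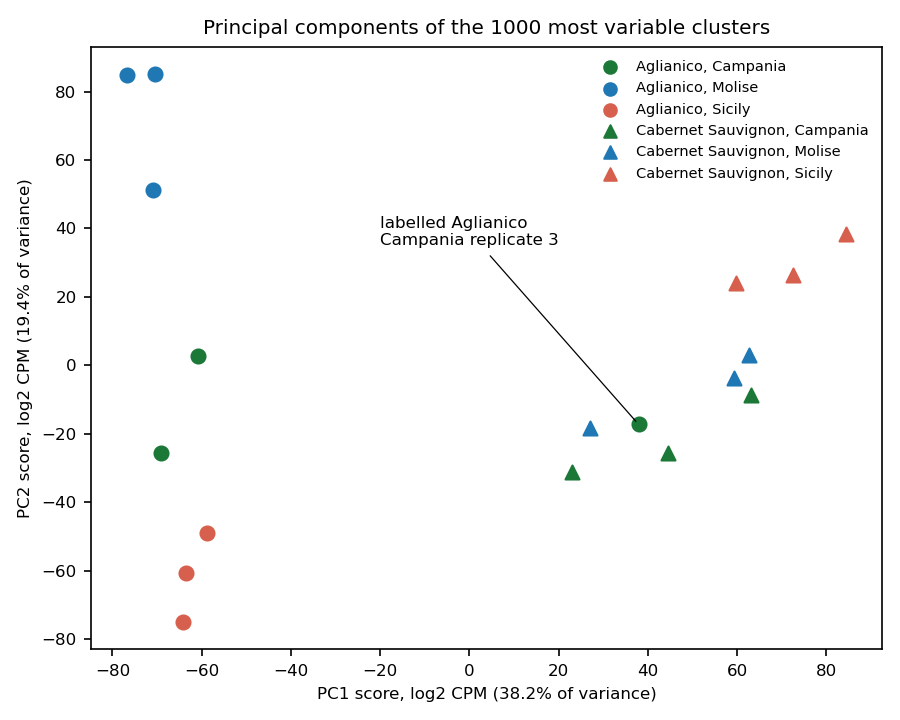
Principal component scores of the 18 libraries, from log2 CPM of the 1000 most variable clusters; colour gives the site and marker shape the variety, 1 point per library. The library labelled Aglianico Campania replicate 3 has a first score of 37.95, and the other Aglianico libraries lie at or below -58.73.

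Clusters found in a single variety gave the same picture. From the Molise and Sicily libraries, 7 clusters were present in Aglianico and absent from Cabernet Sauvignon, and 10 were present in Cabernet Sauvignon and absent from Aglianico. At Campania, replicates 1 and 2 of Aglianico held 7 of the 7 Aglianico clusters and 0 of the 10 Cabernet Sauvignon clusters at 1 CPM or more. The library labelled Aglianico Campania replicate 3 held 0 of the 7 and 10 of the 10. Its mean level of the 10 clusters was 18.54 CPM, beside 16.77 to 18.16 CPM in the 3 Cabernet Sauvignon Campania libraries. The library was kept under its label, and counts that involve Aglianico Campania are also given without it.

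**Figure D2:**
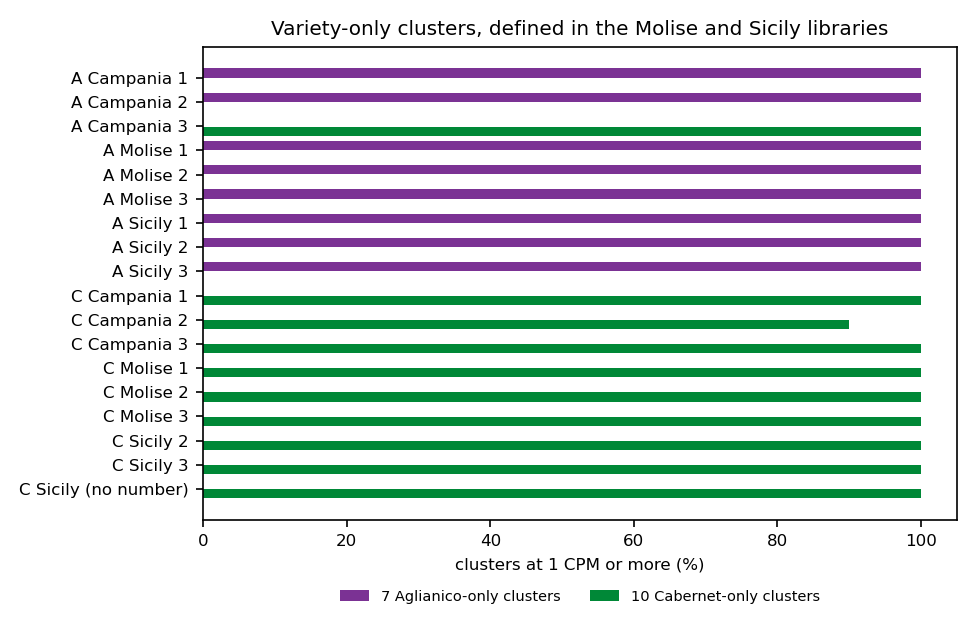
Percent of the 7 Aglianico clusters and of the 10 Cabernet Sauvignon clusters found at 1 CPM or more, for each of the 18 libraries. The clusters were defined in the Molise and Sicily libraries, so the Campania bars are the informative ones; the library labelled Aglianico Campania replicate 3 shows 0% and 100%.

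Cabernet Sauvignon Sicily differed from the other groups in how many transcripts were detected. Replicate 2 had 45103 clusters with 10 or more counts and the unnumbered library 29228, whereas replicate 3 had 23540 and the 15 libraries of other groups had 19173 to 25466. Aglianico Sicily had the most concentrated transcript pool, with 28.8% ± 4.6 of its counts in the 20 most abundant clusters, against 18.3% ± 3 in Aglianico Molise and 15.6% ± 3.8 in Cabernet Sauvignon Sicily (SD, n = 3). Each of these differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 0.23 over 9 comparisons. The 87 clusters that were abundant in some libraries and absent from others held 1.32% to 13.73% of the counts in 8 Aglianico libraries, with the highest values in Aglianico Sicily replicates 3 (13.73%) and 2 (8.3%). They held 0.2% in the library labelled Aglianico Campania replicate 3 and 0% to 0.75% in Cabernet Sauvignon.

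**Figure D3:**
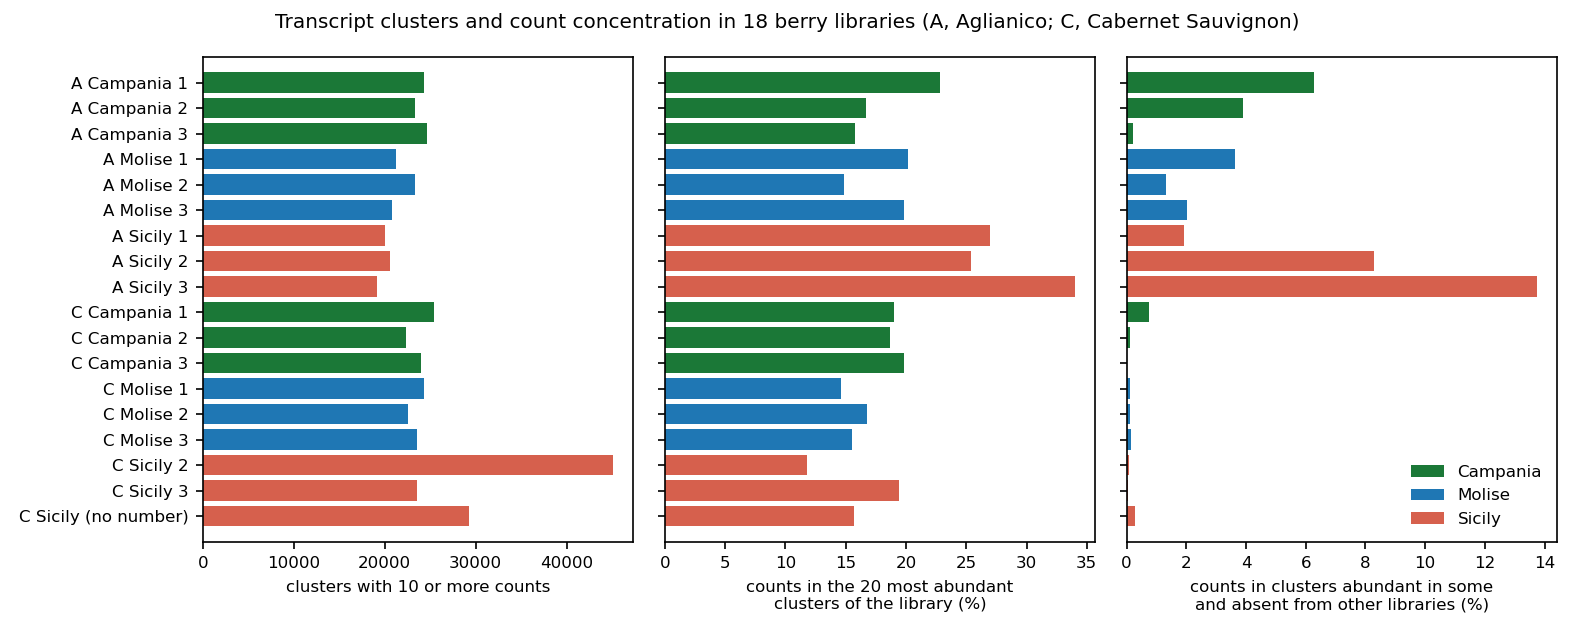
Number of clusters with 10 or more counts, percent of counts in the 20 most abundant clusters, and percent of counts in the 87 clusters that are abundant in some libraries and absent from others, 1 bar per library, coloured by site. Cabernet Sauvignon Sicily replicate 2 reaches 45103 clusters, and Aglianico Sicily replicate 3 holds 13.73% of its counts in the 87 clusters.

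In Aglianico berries, Molise and Campania differed least. Of 27519 clusters, 291 were higher and 195 lower at Molise, with a median absolute log2 fold change of 1.49 among the 486 called. Cluster-27903.5934 averaged 70 ± 19.2 CPM at Molise and had no count at Campania, at least 2080-fold higher (adjusted p = 0.0151). Cluster-27903.58630 averaged 42.3 ± 46.4 CPM against no count, at least 1250-fold higher (adjusted p = 0.0407). Cluster-27903.34611 fell from 37 ± 12.8 CPM at Campania to 0.799 ± 0.377 CPM at Molise (SD, n = 3), a log2 fold change of -5.52 ± 0.72 (SE, adjusted p = 0.00447), and this call held without any 1 library. Cluster-27903.25852 fell from 33 ± 29.4 to 0.319 ± 0.288 CPM, a log2 fold change of -6.67 ± 1.4 (SE, adjusted p = 0.0347). However, Aglianico Campania replicate 1 held only 0.68 CPM, against 58.03 CPM in replicate 2 and 40.32 CPM in the doubted library labelled replicate 3. Among the 1000 most abundant clusters, 21 were higher and 9 lower at Molise.

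The count for Molise against Campania was 207 without Aglianico Molise replicate 1, 67 without Aglianico Molise replicate 3 and 892 without Aglianico Campania replicate 2. Without the library labelled Aglianico Campania replicate 3 it was 413. It was 5 in a fit on these 2 groups, 20 in a fit on Aglianico alone, 74 with no filter and 2284 by DESeq2. The call of Cluster-27903.5934 was lost without Molise replicate 1 (adjusted p = 0.051) or 3 (0.0937). That of Cluster-27903.58630 was lost without Campania replicate 1 (0.0719), Campania replicate 3 (0.0765) or Molise replicate 3 (0.125), and that of Cluster-27903.25852 without Campania replicate 3 (0.0573) or Molise replicate 1 (0.0915), 2 (0.0719) or 3 (0.125). Under upper-quartile scaling 38.9% of calls were higher, against 59.9% under TMM.

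Sicily stood further from Campania in Aglianico, with 1622 clusters higher and 1671 lower and a median absolute log2 fold change of 1.61. Among the 1000 most abundant clusters the calls leaned upwards, with 162 higher and 40 lower at Sicily. Cluster-27903.46352 averaged 97.4 ± 77.1 CPM at Campania and had no count at Sicily, at least 1740-fold lower (adjusted p = 0.00022). Cluster-27903.14449 averaged 113 ± 78.3 CPM at Campania and 0.0208 ± 0.036 CPM at Sicily, where 1 count was found in all (adjusted p = 6.18e-06); the ratio of means was 5440 (95% Poisson interval 1090 to 239000). Both calls held without any 1 library, but that of Cluster-27903.46352 was lost by limma-voom (adjusted p = 0.0737). Both Campania means include the doubted library labelled replicate 3. It held 177.53 CPM of Cluster-27903.46352, against 91.11 and 23.63 CPM in replicates 1 and 2. For Cluster-27903.14449 it held 23.41 CPM, against 167.99 and 147.87 CPM. Cluster-27903.31865 averaged 3380 ± 5440 CPM at Sicily, with 471.11, 1.62 and 9657.76 CPM in the 3 libraries, against 3 counts in all at Campania (ratio 99400, 95% Poisson interval 34200 to 485000, adjusted p = 0.0349). Cluster-27903.32761 averaged 397 ± 379 CPM at Sicily against no count, at least 11800-fold higher (adjusted p = 0.0314). Both higher clusters named here belong to the 87 clusters described above, whose source is left open below.

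The 3293 calls for Sicily against Campania became 2058 without Aglianico Campania replicate 2, 1775 without Sicily replicate 1 and 1464 without Sicily replicate 3, and 4318 without the library labelled Aglianico Campania replicate 3. The calls of the 2 higher clusters were not stable. That of Cluster-27903.31865 was lost without Campania replicate 1 (adjusted p = 0.126), 2 (0.106) or 3 (0.0855) or Sicily replicate 1 (0.0567) or 3 (0.0561). That of Cluster-27903.32761 was lost without Campania replicate 1 (0.0548), 2 (0.0601) or 3 (0.0548) or Sicily replicate 1 (0.105) or 2 (0.0612). Of the calls, 49.3% were higher under TMM, 32.1% under upper-quartile scaling and 67.5% by limma-voom. The count was 1167 with no filter, 1354 in a fit on Aglianico alone and 826 in a fit on these 2 groups.

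The widest site difference in Aglianico was between Sicily and Molise, with 2323 clusters higher and 2409 lower at Sicily (median absolute log2 fold change 1.64). Among the 1000 most abundant clusters 173 were higher and 90 lower. Cluster-27903.5935 averaged 322 ± 244 CPM at Molise and had no count at Sicily, at least 5730-fold lower (adjusted p = 0.00429), a call that held without any 1 library. Cluster-27903.6020 averaged 603 ± 128 CPM at Molise and likewise had no count at Sicily, at least 10700-fold lower (adjusted p = 0.0193). Cluster-27903.32080 averaged 18600 ± 23900 CPM at Sicily, with 45928.14 CPM in replicate 3, and 0.0555 ± 0.0605 CPM at Molise, a ratio of 334000 (adjusted p = 0.0345). Cluster-27903.34138 averaged 9780 ± 10800 CPM against 0.071 ± 0.063 CPM, a ratio of 138000 (adjusted p = 0.0429). Every cluster named for this pair of sites belongs to the 87 clusters described above, whose source is left open below.

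The 4732 calls for Sicily against Molise became 2953 without Aglianico Molise replicate 3, 3139 without Sicily replicate 1 and 2590 without Sicily replicate 3, 2128 with no filter and 2544 in a fit on Aglianico alone; 54.5% of the calls by limma-voom were higher. The calls of Cluster-27903.32080 and Cluster-27903.34138 were lost without any 1 of the 6 libraries, at adjusted p of 0.0507 to 0.109 and 0.051 to 0.125. That of Cluster-27903.6020 was lost without Sicily replicate 1 (adjusted p = 0.0533), 2 (0.0525) or 3 (0.0581). Over the 3 sites together, 5427 clusters differed in Aglianico, and Sicily was the site that stood apart for 57.7% of them. That total became 1990 with no filter, 2045 in a fit on Aglianico alone, 3589 without Molise replicate 3, and 3277, 3526 and 2783 without Sicily replicates 1, 2 and 3.

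In Cabernet Sauvignon berries, Molise and Campania gave the fewest calls with all libraries, 614 clusters higher and 483 lower at Molise, but this order was not stable. The median absolute log2 fold change was 1.17, and 43 of the 1000 most abundant clusters were higher and 20 lower. Cluster-27903.59677 averaged 13.9 ± 10.6 CPM at Molise and had no count at Campania, at least 404-fold higher (adjusted p = 0.0301). Cluster-27903.42040, a member of the 87 clusters described above, averaged 196 ± 288 CPM against 1.17 ± 1.57 CPM, a log2 fold change of 7.38 ± 1.91 (SE, adjusted p = 0.0499). Cluster-27903.29897 fell from 18.6 ± 5.51 to 1.33 ± 0.393 CPM, a log2 fold change of -3.8 ± 0.87 (SE, adjusted p = 0.0301). Cluster-27903.38769 fell from 13.5 ± 1.81 to 1.1 ± 0.0604 CPM, a log2 fold change of -3.61 ± 0.69 (SE, adjusted p = 0.0177).

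All 4 of these calls were lost without any 1 of the 6 libraries, at adjusted p of 0.0795 to 0.0961, 0.0928 to 0.169, 0.0768 to 0.137 and 0.054 to 0.0877 in the order given, while the log2 fold changes kept their sign. The 1097 calls became 35, 128 and 88 without Cabernet Sauvignon Campania replicates 1, 2 and 3, and 60, 108 and 114 without Molise replicates 1, 2 and 3. Without the 3 doubted libraries, none of which belonged to these 2 groups, there were 2339, and without the 2 Cabernet Sauvignon Sicily libraries 942. Sicily is 1 library in those fits, so their counts do not rank the 3 pairs. In fits on 2 groups with 3 libraries each, the order reversed, with 5066 for Molise against Campania, 3464 for Sicily against Campania and 3769 for Sicily against Molise. The count for Molise against Campania was 147 with no filter, 2784 in a fit on Cabernet Sauvignon alone and 2962 by DESeq2.

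Between Sicily and Campania in Cabernet Sauvignon, 3126 clusters were higher and 1587 lower at Sicily under TMM (median absolute log2 fold change 1.82). Upper-quartile scaling gave 2646 higher and 2708 lower, so the lean to higher levels depended on the scaling. Among the 1000 most abundant clusters 196 were higher and 19 lower. Cluster-27903.16794 averaged 33 ± 17.4 CPM at Sicily and had no count at Campania, at least 964-fold higher (adjusted p = 0.00107), and the call held without any 1 library. Cluster-27903.14308 averaged 194 ± 329 CPM at Sicily against no count, at least 5650-fold higher (adjusted p = 0.0223). Replicate 2 held 573.16 CPM and the other libraries 7.76 and 0.48 CPM, so this bound applies to the mean only. The cluster is a member of the 87 clusters described above. Cluster-27903.27798 averaged 14.7 ± 4.5 CPM at Campania and had no count at Sicily, at least 369-fold lower (adjusted p = 0.0262). Cluster-27903.38702 averaged 17.1 ± 17.7 CPM at Campania against 1 count in all at Sicily (ratio 1340, 95% Poisson interval 231 to 50900, adjusted p = 0.00245).

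Without both Cabernet Sauvignon Sicily replicate 2 and the unnumbered library, the 4713 calls for Sicily against Campania became 340 higher and 49 lower, with the 1 remaining library assumed to vary like the other groups. Clusters found in those 2 libraries alone could not be among the 4713, since the filter required enough counts in at least 3 libraries. Whether the extra transcripts acted in another way, or the smaller number of libraries caused this fall, was not tested. The count was 3192 without replicate 2 alone, 3660 without the unnumbered library alone and 2113 with no filter. Single libraries that moved it more were Campania replicates 1, 2 and 3 (2700, 3117 and 2565 without each). The call of Cluster-27903.14308 was lost without Campania replicate 1 (adjusted p = 0.0588), 2 (0.0556) or 3 (0.0626), and that of Cluster-27903.27798 without any 1 of the 6 libraries (0.0509 to 0.0825). Without the 2 Sicily libraries, the calls of Cluster-27903.27798 (0.346) and Cluster-27903.38702 (0.16) were lost, the latter also by limma-voom (0.0882). Under upper-quartile scaling 49.4% of calls were higher, against 66.3% under TMM.

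Against Molise, Cabernet Sauvignon berries from Sicily again showed more clusters higher (2787) than lower (1773) under TMM. Of the 1000 most abundant clusters, 178 were higher and 41 lower. Cluster-27903.49637 averaged 15.4 ± 19.4 CPM at Sicily and had no count at Molise, at least 454-fold higher (adjusted p = 0.00373); the call held without any 1 library but was lost in a fit on the 2 groups (0.0909) and by limma-voom (0.0947). Cluster-27903.52260 averaged 22 ± 37.3 CPM against no count, at least 648-fold higher (adjusted p = 0.0238), with 65.07 CPM in replicate 2 and 0.64 and 0.24 CPM in the other two. Cluster-27903.59677 averaged 13.9 ± 10.6 CPM at Molise and had no count at Sicily, at least 349-fold lower (adjusted p = 0.0119). Cluster-27903.27798 averaged 10.3 ± 2.64 CPM at Molise against no count, at least 259-fold lower (adjusted p = 0.0324).

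The 4560 calls for Sicily against Molise became 1768, 2479 and 1734 without Cabernet Sauvignon Molise replicates 1, 2 and 3, 1672 with no filter, and 261 higher and 58 lower without Sicily replicate 2 and the unnumbered library, which leaves 1 library at Sicily. The call of Cluster-27903.52260 was lost without Molise replicate 1 (adjusted p = 0.0727), 2 (0.064) or 3 (0.0746) and without the 2 Sicily libraries (0.103). That of Cluster-27903.27798 was lost without any 1 of the 6 libraries (0.0619 to 0.089), and without the 2 Sicily libraries (0.354), as was that of Cluster-27903.59677 (0.187). Under upper-quartile scaling 44.5% of calls were higher, against 61.1% under TMM. Over the 3 sites 6463 clusters differed in Cabernet Sauvignon, and Sicily stood apart for 55.3% of them, 2558 higher there and 1013 lower. With the 1 Sicily library left without those 2, the total was 1319. Without the 3 doubted libraries, Molise stood apart for 39.6% of 2887 clusters and Sicily for 31.8%, so the leading site changed, but with 1 library at Sicily against 3 at each other site these shares do not rank the sites.

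**Figure D4:**
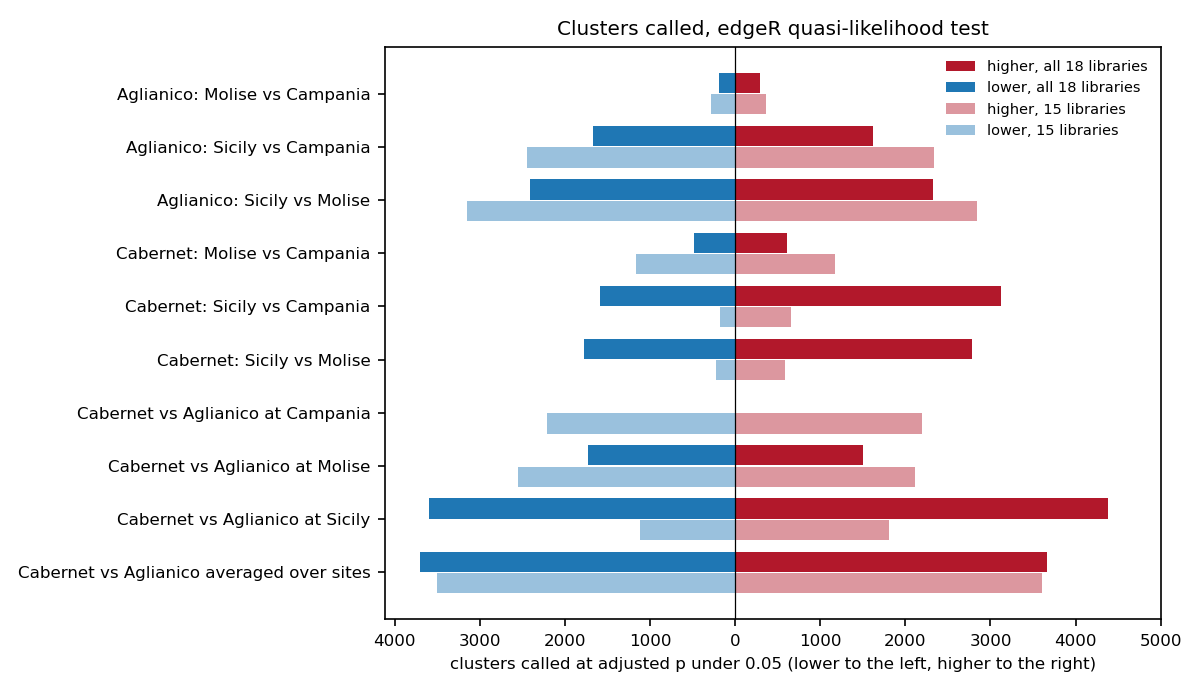
Number of clusters called higher (to the right) and lower (to the left) in each comparison at an adjusted p under 0.05 (edgeR), with all 18 libraries in full colour and with 15 libraries in pale colour, after leaving out the library labelled Aglianico Campania replicate 3 and 2 Cabernet Sauvignon Sicily libraries, which leaves 1 library in that group. At Campania the varieties differed by 0 clusters with 18 libraries and by 4409 with 15.

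The same site contrast was then compared between the varieties, which share no library but come from 1 fit. For Molise against Campania, 65 clusters were higher and 19 lower in both varieties, where independent lists would share 6.5 and 3.4, and 1 was called in opposite directions (9.5 for independent lists). For Sicily against Molise, 409 were higher and 421 lower in both (235.3 and 155.2 for independent lists) and 204 were opposite (393.6). For Sicily against Campania the counts lay nearer to those of independent lists, at 233 higher, 176 lower and 199 opposite (184.2, 96.4 and 283.4). Across clusters, which are not independent replicates, Pearson's r between the varieties' log2 fold changes was 0.31 for Molise against Campania and -0.02 for both contrasts with Sicily (Spearman's rho 0.4, 0.11 for Sicily against Molise and 0.09 for Sicily against Campania). Without the 3 doubted libraries, Sicily against Molise gave 218 higher, 120 lower and 52 opposite (52.4, 22.6 and 78.5 for independent lists). Molise against Campania gave 85, 29 and 34 (13.4, 10.2 and 23.5), and Sicily against Campania 99, 50 and 72 (47.9, 13.9 and 63.4), so in these 2 contrasts opposite calls were also more than in independent lists, with 1 Cabernet Sauvignon library at Sicily. Pearson's r was then 0.19 for Molise against Campania, 0 for Sicily against Campania and 0.06 for Sicily against Molise.

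The interaction tests asked whether a site difference itself differed between the varieties. Overall 3783 clusters showed an interaction of variety and site. For Sicily against Campania, 2499 clusters had a higher log2 fold change in Cabernet Sauvignon than in Aglianico and 1318 a lower one, with a median absolute difference of 2.64. Limma-voom turned this balance, with 1069 higher and 1252 lower. For Sicily against Molise the numbers were 2031 and 1147, with a median absolute difference of 2.75. For Molise against Campania they were 7 and 1, where 3326 clusters had an unadjusted p under 0.05.

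The interaction counts rested on several libraries. The overall count was 6007 without the library labelled Aglianico Campania replicate 3, 1615, 1917 and 1573 without Aglianico Sicily replicates 1, 2 and 3, 2440, 2369 and 2439 without Cabernet Sauvignon Campania replicates 1, 2 and 3, 2293, 2513 and 2361 without Cabernet Sauvignon Molise replicates 1, 2 and 3, and 2509 without Cabernet Sauvignon Sicily replicate 2. With no filter it was 1045, by limma-voom 2515 and by DESeq2 5730. Without Cabernet Sauvignon Sicily replicate 2 and the unnumbered library, which leaves 1 library there, it was 433, and without these and the library labelled Aglianico Campania replicate 3 it was 2319. For Sicily against Campania the count was 2308 and 5988 without Aglianico Campania replicate 2 and the library labelled replicate 3, 2283 and 2047 without Aglianico Sicily replicates 1 and 3, 2300, 2198 and 2174 without Cabernet Sauvignon Campania replicates 1, 2 and 3, and 2512 without Cabernet Sauvignon Sicily replicate 2. For Sicily against Molise it was 1892 without Aglianico Molise replicate 2, 1701, 1935 and 1679 without Aglianico Sicily replicates 1, 2 and 3, and 1465, 1819 and 1561 without Cabernet Sauvignon Molise replicates 1, 2 and 3. For Molise against Campania it was 50, 2 and 523 without Aglianico Campania replicates 1, 2 and the library labelled 3, 1, 58 and 0 without Aglianico Molise replicates 1, 2 and 3, and 0 without any 1 of the 6 Cabernet Sauvignon libraries of these sites. At those 0 counts from edgeR, 2370 to 3079 clusters had an unadjusted p under 0.05. With all libraries DESeq2 called 811 and limma-voom 9 for this contrast.

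The varieties were compared at each site. At Molise, 1499 clusters were higher and 1727 lower in Cabernet Sauvignon than in Aglianico, with a median absolute log2 fold change of 1.56, and 51 of the 1000 most abundant clusters were higher and 98 lower. Cluster-27903.27032 averaged 115 ± 19.1 CPM in Cabernet Sauvignon and had no count in Aglianico, at least 2630-fold higher (adjusted p = 0.0143). Cluster-27903.28907 averaged 88.9 ± 19.1 CPM against no count, at least 2030-fold higher (adjusted p = 0.0167). Aglianico Sicily held 40.35 to 133.24 CPM of the first and 10.1 to 136.85 CPM of the second, while Aglianico Campania replicate 1 had 0 CPM of both. Cluster-27903.32361 averaged 4530 ± 4940 CPM in Aglianico and 1 count in all in Cabernet Sauvignon, a ratio of 435000 (95% Poisson interval 71900 to 15800000, adjusted p = 0.00413); the call held without any 1 library but was lost by limma-voom (0.377). Cluster-27903.36186 averaged 1570 ± 2040 CPM in Aglianico against no count in Cabernet Sauvignon, at least 46200-fold lower (adjusted p = 0.0249). Both lower clusters named here belong to the 87 clusters described above, whose source is left open below.

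The 3226 calls at Molise became 1454 and 824 without Aglianico Molise replicates 1 and 3, 564, 1225 and 1306 without Cabernet Sauvignon Molise replicates 1, 2 and 3, and 770 with no filter. Limma-voom lost all 4 named calls. The call of Cluster-27903.27032 was also lost without Aglianico Molise replicate 3 (adjusted p = 0.054), and that of Cluster-27903.28907 without the same library (0.0604) or Cabernet Sauvignon Molise replicate 1 (0.0548). That of Cluster-27903.36186 was lost without Aglianico Molise replicate 1 (0.0512) or 3 (0.0509) or Cabernet Sauvignon Molise replicate 1 (0.0874), 2 (0.0673) or 3 (0.0661). Under upper-quartile scaling 58.1% of calls were higher in Cabernet Sauvignon, against 46.5% under TMM.

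With all libraries the varieties differed by the most clusters at Sicily, with 4382 higher and 3603 lower in Cabernet Sauvignon (2895 and 3120 by limma-voom) and a median absolute log2 fold change of 1.71. Among the 1000 most abundant clusters 152 were higher and 190 lower. Cluster-27903.14308 averaged 194 ± 329 CPM in Cabernet Sauvignon and had no count in Aglianico, at least 3460-fold higher (adjusted p = 0.0171). Cluster-27903.13534 averaged 150 ± 257 CPM against no count, at least 2670-fold higher (adjusted p = 0.0241), of which 446.89 CPM came from replicate 2. Cluster-27903.31865 averaged 3380 ± 5440 CPM in Aglianico and had no count in Cabernet Sauvignon, at least 84900-fold lower (adjusted p = 0.0163). Its Aglianico Sicily libraries held 471.11, 1.62 and 9657.76 CPM, so this bound applies to the mean only. Cluster-27903.33734 averaged 2900 ± 4340 CPM in Aglianico against no count, at least 73000-fold lower (adjusted p = 0.0497). All clusters named here except Cluster-27903.13534 belong to the 87 clusters described above, whose source is left open below.

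Without Cabernet Sauvignon Sicily replicate 2 and the unnumbered library, 1066 clusters were higher and 483 lower at Sicily. Without these and the library labelled Aglianico Campania replicate 3, there were 2925 calls at Sicily, 4660 at Molise and 4409 at Campania. Both fits set 1 Cabernet Sauvignon library against 3 at Sicily, so they do not rank the sites. With no filter 4929 were called at Sicily. Without the 2 Sicily libraries, the calls of Cluster-27903.31865 (adjusted p = 0.218) and Cluster-27903.33734 (0.363) were lost. The call of Cluster-27903.13534 was lost without Aglianico Sicily replicate 1 (0.0584), 2 (0.0551) or 3 (0.0591), and that of Cluster-27903.31865 without Cabernet Sauvignon Sicily replicate 2 (0.0537). That of Cluster-27903.33734 was lost without any 1 of the 6 libraries (0.0521 to 0.128), and under RLE (0.0503) and upper-quartile scaling (0.0522).

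At Campania the edgeR test called 0 clusters between the varieties, while 3868 had an unadjusted p under 0.05. DESeq2 called 835 and limma-voom 0. Without the library labelled Aglianico Campania replicate 3, edgeR called 2070 clusters higher and 1953 lower in Cabernet Sauvignon. Without this library and the 2 Cabernet Sauvignon Sicily libraries, 2198 were higher and 2211 lower, with a median absolute log2 fold change of 1.64.

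Averaged over the 3 sites, 3669 clusters were higher and 3710 lower in Cabernet Sauvignon (8960 calls without the library labelled Aglianico Campania replicate 3). The median absolute log2 fold change with all libraries was 0.92. Among the 1000 most abundant clusters 100 were higher and 221 lower. At Molise and Sicily, which share no library, 537 clusters were higher and 728 lower in Cabernet Sauvignon at both sites, where independent lists would share 238.7 and 226.1, and 195 were opposite (471.3 for independent lists). In the 15 libraries without the 3 left out above, 301 clusters were higher and 273 lower in Cabernet Sauvignon at all 3 sites, where independent lists would share 8.2 and 6.2. No single library moved the averaged count by more than 1.5 times, and it was 4387 without Cabernet Sauvignon Sicily replicate 2 and the unnumbered library and 3894 with no filter.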

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

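The tests of an exchange, a wrong label, a mixture, depth, growth at Sicily, variety or genotype, and the shuffle within variety and site were chosen only after the result had been seen. The fits without 2 or 3 libraries, and the definitions of the patterns, were likewise chosen after seeing the data.

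Site differences were not alike in the varieties: the test of the difference itself gave 3783 clusters over the 3 sites, 3817 for Sicily against Campania, 3178 for Sicily against Molise and 8 for Molise against Campania. Among 50 splits of the libraries, 1 gave as many clusters as the real grouping in each of the first 3 cases, the real one itself. The highest of the others were 56, 102 and 429. These splits shuffled all 18 libraries over the 6 groups, so chance assignment to the groups can be excluded. They also mixed varieties and sites, and so cannot separate an interaction from plain differences between varieties or sites. For Molise against Campania 2 of the 50 gave as many, and another split gave 70 clusters against the real 8. The real count became 523 without the library labelled Aglianico Campania replicate 3. What gave the 70 was not tested. The overall count fell to 433 without 2 Cabernet Sauvignon Sicily libraries, which leaves 1 in that group, and rose to 6007 without the library labelled Aglianico Campania replicate 3.

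The library labelled Aglianico Campania replicate 3 sat with Cabernet Sauvignon. An exchange with a Cabernet Sauvignon Campania library would leave an Aglianico profile there, but the highest share of Aglianico clusters in those 3 libraries was 0%. A mixture of RNA of both varieties in similar amounts is argued against by the mean level of the Aglianico clusters, 0% of that in replicates 1 and 2. That level was 12.04 and 37.47 CPM in these replicates. It varied widely among the Aglianico libraries of the other sites, from 9 CPM in Sicily replicate 1 to 457 CPM in Molise replicate 1. A wrong variety label, or an exchange with a Cabernet Sauvignon sample outside the table, remains a candidate explanation: 100% of the Cabernet Sauvignon clusters were present. No biological explanation was tested.

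In Cabernet Sauvignon Sicily, replicate 2 held 6236 clusters with at least 20 counts there and at most 1 in any other library, and the unnumbered library held 5491, against 27 or fewer elsewhere. Greater depth was first tested by thinning all libraries to the smallest total, a test at first judged to decide nothing. Replicate 2 then had 41875 clusters with 10 or more counts and the unnumbered library 28374, against 24883 in the highest other library. These were 1.68 and 1.14 times as many. An excess that remains at equal totals argues against depth, more clearly for replicate 2. A second test, added after that result, argues against depth, since the 4 libraries with larger totals held at most 0 clusters of this kind. Growth at Sicily as such was left open. A first test, on clusters chosen for their absence from the other Sicily libraries, could decide nothing and was replaced. Clusters with at least 20 counts in the library and at most 1 in each of the 12 Campania and Molise libraries numbered 7766 for replicate 2 and 5917 for the unnumbered library. Of these the 3 Aglianico Sicily libraries had a count in 0.02% to 1.55%, and Cabernet Sauvignon Sicily replicate 3 in 0.42% of those of the unnumbered library. Replicate 3 had a count in 26.14% of those of replicate 2, though 20 or more in only 29 of the 7766. Replicate 2 and the unnumbered library had a count in 10.12% and 12.04% of each other's, with 20 or more in 82 clusters. The limit for excluding growth at Sicily was under 10% in every other Sicily library, which 3 of these values did not meet. Reads from another organism or source, added to a grape profile, may explain the pattern. Over 13476 shared clusters, replicate 2 and the unnumbered library correlated with replicate 3 at 0.957 and 0.978 (mean 0.968). Pairs in other groups lay at 0.955 to 0.989 without the library labelled Aglianico Campania replicate 3, whose pairs had 0.911 and 0.917. The pairs within Cabernet Sauvignon Campania and Molise lay at 0.979 to 0.989, above every pair within Cabernet Sauvignon Sicily. The mean value therefore does not show an unchanged grape profile in replicate 2 and the unnumbered library. Counted with at most 1 count in the 16 other libraries, the extra clusters were 6532 and 5902, with 73 in both. No sequence was used here to name a source.

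For the 87 clusters abundant in some libraries and absent from others, the median correlation of each with its nearest partner was 0.98. A first comparison, with libraries shuffled throughout (highest 0.69), removed variety and site as well and was replaced. With replicates shuffled within each variety and site, 100 sets had a median of 0.92 and a highest value of 0.96, so clusters also moved together among replicates. That is compatible with a few sources that each bring several clusters, but fragments of 1 transcript, or grape transcripts regulated together, would do the same. Grape variety or genotype alone cannot be told apart from such sources for the clusters that do not part replicates: 47.1% (41 of 87) were present in 1 replicate and absent from another of the same group, short of the 50% set for excluding it. This count left out Aglianico Campania and Cabernet Sauvignon Sicily, the groups with doubted libraries, so 41 is a minimum. Cluster-27903.6020, which parted no replicates in the groups counted, had 0 and 93.27 CPM in Aglianico Campania replicates 1 and 2. The share over all undoubted libraries was not computed. Of the 87, 78 reached 10 CPM in an Aglianico library and 16 in a Cabernet Sauvignon library, leaving out the 3 libraries above. Viruses or other organisms living on the berries are possible sources, and no sequence was used here to test them. Of the 32 named calls, 19 were of clusters outside the 87, and the remaining named calls share this open question. The limit of 500 CPM does not clear the calls outside the 87. Cluster-27903.13534, for instance, had 446.89 CPM in Cabernet Sauvignon Sicily replicate 2, against 1.73 CPM in replicate 3 and 0.29 CPM in the unnumbered library. The source of the clusters outside the 87 was not tested either.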

How the results depend on the processing

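The fits without 2 or 3 libraries, without the 87 clusters and without a block over 17 libraries were chosen after seeing the data. The tests of the 32 gene lists, with an estimated correlation, a replicate block or members of at least 1 CPM, were not run because the clusters carry no gene names. For the named clusters, 209 of 674 values under alternatives no longer passed the threshold. None changed direction, which says little, since these clusters were chosen for large changes with no overlap between the groups. Of 32 named calls, 23 were lost with no filter, 22 by limma-voom, 13 with the replicate block, 7 without it over 17 libraries, and 14 and 13 without 2 and 3 libraries; 10 of 30 were lost in fits on 2 groups and 8 of 24 in fits on 1 variety. For the balance of higher and lower calls, in 42 of 280 counts under alternatives the larger part was on the other side, 14 of them for the averaged variety difference (49.7% higher as reported) and 10 for Aglianico Sicily against Campania (49.3%). Upper-quartile scaling turned Aglianico Molise against Campania (59.9% to 38.9%), Cabernet Sauvignon Sicily against Molise (61.1% to 44.5%) and Campania (66.3% to 49.4%) and the varieties at Molise (46.5% to 58.1%). Limma-voom turned the interaction of Sicily against Campania (65.5% to 46.1%), Aglianico Sicily against Campania (49.3% to 67.5%) and Molise (49.1% to 54.5%), the varieties at Sicily (54.9% to 48.1%) and the averaged difference (49.7% to 50.3%). Counts under RLE scaling, upper-quartile scaling, no robust shrinkage and library sizes without the 20 most abundant clusters stayed within 1.5 times of those reported. Upper-quartile scaling shifted the median log2 fold change by -0.11 and -0.151 for Molise and Sicily against Campania in Aglianico, by -0.157 and -0.148 for Sicily against Campania and Molise in Cabernet Sauvignon, and by 0.101 and -0.108 for the interactions of Molise against Campania and Sicily against Molise. The counts below moved by more; the cause was not tested except where fewer libraries or more clusters tested are the change itself.

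With no filter (97339 clusters tested), counts were 74, 1167 and 2128 in Aglianico (Molise against Campania, Sicily against Campania, Sicily against Molise) and 147, 2113 and 1672 in Cabernet Sauvignon. They were 770 and 4929 between varieties at Molise and Sicily, 1990 for any site difference in Aglianico, 1045 for the overall interaction, 0, 1286 and 989 for its 3 contrasts in the same order, and 3894 for the averaged variety difference. At that 0 from edgeR, 3844 clusters had an unadjusted p under 0.05, and DESeq2 on 97339 clusters called 811 and limma-voom on 27519 called 9. With 1 CPM in 3 libraries the interaction of Molise against Campania gave 13. A fold threshold left 653 for Cabernet Sauvignon Molise against Campania and 3434 for the averaged difference. DESeq2 called 2284 and 2962 for Molise against Campania in Aglianico and Cabernet Sauvignon, 835 between varieties at Campania and 5730 for the overall interaction. Limma-voom called 2515 for the overall interaction, 2321 for its contrast of Sicily against Campania and 1961 for Sicily against Molise. Fits on Aglianico alone gave 20, 1354, 2544 and, for any site, 2045; the fit on Cabernet Sauvignon alone gave 2784 for Molise against Campania. Fits on 2 groups gave 5 and 826 for Molise and Sicily against Campania in Aglianico and 5066 for Molise against Campania in Cabernet Sauvignon.

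The replicate block (17 numbered libraries) gave 2854 for Cabernet Sauvignon Sicily against Molise, 1 between varieties at Campania and 2 for the interaction of Molise against Campania, and moved no other count by over 1.5 times; without a block the same libraries gave 3147, 0 and 3, so most of the fall in the first and the last came with the unnumbered library left out. The labels do not say that a number is shared. Deviations of libraries with the same number correlated at -0.13 to 0.32 (median 0.05, 40 pairs), and 8 of 17 libraries matched best with their own number, so the numbers were not taken as pairs.

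Without 2 Cabernet Sauvignon Sicily libraries, counts were 389 and 319 for Sicily against Campania and Molise in Cabernet Sauvignon, 1549 between varieties at Sicily, 1319 for any site in Cabernet Sauvignon, 433 for the overall interaction, 449 and 503 for its contrasts of Sicily against Campania and Molise, and 4387 for the averaged difference. Without 3 libraries they were 2339, 837 and 821 in Cabernet Sauvignon (2975 for any site), 4409 and 2925 between varieties at Campania and Sicily, 2319 for the overall interaction and 647, 2166 and 1172 for its contrasts. Both fits leave 1 Cabernet Sauvignon Sicily library, so fewer calls there may come from fewer libraries. Without the 87 clusters the interaction of Molise against Campania gave 5.

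Leaving out each library in turn gave 67 to 892, 1464 to 4318 and 2590 to 3502 in Aglianico and 2783 to 6467 for any site. In Cabernet Sauvignon it gave 35 to 128, 2565 to 4906 and 1734 to 4485. Between varieties it gave 0 to 4023 at Campania and 564 to 2513 at Molise, and for the interaction 1573 to 6007 overall and 0 to 523, 2047 to 5988 and 1465 to 3563 by contrast. At the 0 counts from edgeR at Campania with 1 library left out, 2066 to 3363 clusters had an unadjusted p under 0.05. With all libraries edgeR also called 0 at Campania, where 3868 had an unadjusted p under 0.05, DESeq2 called 835 and limma-voom 0. Any site difference in Cabernet Sauvignon, the varieties at Sicily and the averaged difference stayed within 1.5 times. Depth limits statements of absence: a group with no count could hold up to 0.0337 to 0.0561 CPM.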

Other observations

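Presence and absence of transcripts differed more between Aglianico sites than between Cabernet Sauvignon sites. Between Aglianico Molise and Aglianico Sicily, 74 clusters had at least 5 CPM in every library of 1 group and no count in the other, 42 of them present at Molise and 32 at Sicily, and 14 of the 74 belonged to the 87 clusters described above. With all libraries the number was 8 for Aglianico Campania and Molise and 13 for Aglianico Campania and Sicily, and Cabernet Sauvignon sites differed by 1 (Campania and Molise), 5 (Campania and Sicily) and 3 (Molise and Sicily). Without the 3 doubted libraries, the numbers were 29 and 21 in Aglianico and 1, 8 and 5 in Cabernet Sauvignon. Between the varieties the number was 0 at Campania, 88 at Molise and 83 at Sicily with all libraries, and 49, 88 and 124 without the 3 doubted ones. Fewer libraries make presence or absence in a whole group easier to meet, and 1 Cabernet Sauvignon library is then left at Sicily. These differences were not tested.

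Replicates correlated across clusters at 0.943 to 0.951 in Aglianico and 0.964 to 0.975 in Cabernet Sauvignon at Molise. At Campania they correlated at 0.941 for Aglianico replicates 1 and 2, 0.884 and 0.891 for these with the library labelled 3, and 0.952 to 0.969 in Cabernet Sauvignon. At Sicily the values were 0.955 to 0.962 in Aglianico; within Cabernet Sauvignon they were 0.929 and 0.921 for replicate 2 with the others and 0.966 for replicate 3 with the unnumbered library. Site took 52.1% of the variance among the 9 Aglianico libraries and 59.1% among the 9 Cabernet Sauvignon libraries, and 61% and 58.5% after leaving out the doubted libraries of each variety.

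Other splits of the libraries were counted for each test. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 486 and 90 for Aglianico Molise against Campania, 3293 and 3 for Sicily against Campania, and 4732 and 0 for Sicily against Molise. They were 1097, 4713 and 4560 in Cabernet Sauvignon, each with 0 as the highest other, and 3226 and 7985 between the varieties at Molise and Sicily, again with 0. In these 8 tests 1 of the 10 splits, the real one, gave as many. Between the varieties at Campania the real count was 0, so 10 of the 10 splits gave as many, and another split gave 21. Chance assignment can be excluded for any site difference in Aglianico (5427, highest other 853), any site difference in Cabernet Sauvignon (6463, highest other 2710) and the averaged variety difference (7379, highest other 1957), where 1 of 50 splits gave as many.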
